A study of Mus musculus with 21 samples.

How the data were processed

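RNA from mouse bone marrow-derived macrophages was measured by paired-end sequencing. Per the submitters' notes, marrow cells were grown for 5 days in medium conditioned with M-CSF and then held for 36 h with IL-33, IL-4 or no added cytokine. Libraries were prepared from 1 ug of RNA with a NEBNext Ultra kit and read as 150-base pairs on an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.6.1 and DESeq2 1.22.2 with the GRCm38 (mm10) mouse assembly. The gene annotation and the strandedness used for counting were not given in the sources used. The values analysed were deposited read counts per gene, supplied as 1 table of 47069 genes and 21 libraries. Of the 47069 gene identifiers, 46574 were present in GENCODE release M21, which supplied positions and gene types; 495 were not matched.

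The libraries formed 7 groups of 3: wild-type cells with no cytokine, IL-33 or IL-4, cells labelled ST2-/- with no cytokine or IL-33, and cells labelled Cx3cr1-Cre with floxed Gata3 with no cytokine or IL-33. Because gene-level counts did not check either deletion, these last 4 groups are called ST2KO-labelled and floxed-labelled throughout. The replicate number was taken from the last digit of each sample title, and nothing in the labels says whether libraries with different numbers came from separate animals. The p-values therefore measure the spread between these libraries, which may be partly technical.

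Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filterByExpr rule of edgeR with the 7 groups, which left 14473 genes holding at least 99.97% of the counts of every library. All 21 libraries entered 1 quasi-likelihood fit with a mean for each group and TMM normalization. The common dispersion was 0.00740, a coefficient of variation of 0.0860 beyond counting error, with 14 residual degrees of freedom. Tests were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Levels are given as counts scaled to library size by edgeR (CPM), mean ± standard deviation over 3 libraries, and changes as log2 values ± standard error or as folds. When 1 group held no counts, the fold was given as at least that with 3 counts per library there. When a group held only a few counts, the ratio was given with a 95% interval for counting error. Such intervals and floors leave out the spread between libraries.

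There were 9 planned comparisons: IL-33 and IL-4 each against no cytokine in wild-type cells, IL-33 against IL-4, IL-33 against no cytokine in each labelled genotype, the difference between each of these responses and that of the wild type (an interaction test), and each labelled genotype against the wild type without cytokine. The comparison of floxed-labelled with wild-type cells under IL-33 was added after the data had been seen. So were fits without genes of the sex chromosomes and without genes near Il1rl1. The comparisons, gene lists and alternatives were otherwise chosen before the data were examined.

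Genes named in every comparison where measured were Il1rl1, Gata3, Cx3cr1, Il33, Ucp2, Acod1 (given under its older symbol Irg1), Arg1, Chil3 and Retnla. Further genes were drawn from the largest called rises and falls among protein-coding genes with an average of at least 2 log2 CPM and no overlap between the libraries of the groups compared. For 3 against 3 libraries an unchanged gene has a 10% chance of showing no overlap. Leading members of gene lists were also drawn on, and not every gene so reached is printed. Of the genes reached, 1 is not reported here. Genes brought in outside this rule are described as chosen after their values had been seen. Of 347 genes checked, 89 shared some exon sequence with another gene and 8 shared at least 20%, so the counts of Itgam, Sox4, Cdkn1c and Bnip3 among others were treated as uncertain.

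A set of 29 gene lists was fixed by hand from general knowledge. They covered alternative activation, inflammatory cytokines, NF-kB targets, interferon-stimulated genes, glycolysis, the TCA cycle, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, mitochondrial carriers, mitochondrial biogenesis and mitophagy, fatty acid uptake and oxidation, cholesterol synthesis, itaconate and Nrf2 targets, hypoxia, the unfolded protein response, cell cycle, cytokine receptors with GATA factors, apoptotic cell clearance, MHC class II, osteoclasts, the macrophage core and monocytes. Other lists marked neutrophils, mast cells and basophils, eosinophils, dendritic cells, lymphocytes, stromal cells, and erythroid cells with megakaryocytes. Each list was tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes and again with a correlation estimated from the data. Counts of called members use the adjustment over all tested genes unless described as adjusted over the list alone.

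The tests were tried on simulated counts of 13877 genes. The 200 changed genes had means of at least 1.039 CPM, and lower genes were not tried. For 3 against 3 libraries, 77.6%, 94.0% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 5 false calls. For the ST2 interaction the shares were 61.2%, 83.6% and 98.5% with 8 false calls, and for the Gata3 interaction 62.7%, 77.6% and 97.0% with 6. The 2 unchanged comparisons gave 0 calls with edgeR and limma-voom and 1 with DESeq2, in ST2KO-labelled cells. A glycolysis list of 16 genes moved by 1.3-fold was found by camera, which also called 2 lists not moved as such. Camera was not tried on lists as correlated as the real ones (0.499 for glycolysis with IL-33 in the wild type). DESeq2 made 19 to 22 false calls in the 3 changed comparisons.

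Alternatives tried for each comparison were DESeq2 1.42.0 with its own size factors and filtering, RLE and upper-quartile normalization, no filter, a filter of 2 CPM in 3 libraries, a fit of only the groups compared, limma-voom, a block for the replicate number, and omission of each library in turn. Lists were also tested with fry. Exon-level signal, variants in the reads and other data of this study were not analysed here.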

Results

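The data set held 21 RNA sequencing libraries of bone marrow-derived macrophages, 3 in each of 7 groups. Depth ranged from 32.6 to 48.7 M (mega) counted reads. The 3 libraries of each group held 36.0, 37.8 and 39.3 M (wild type, no cytokine), 38.7, 41.7 and 36.6 M (wild type, IL-33) and 32.6, 42.2 and 46.4 M (wild type, IL-4). Those of ST2KO-labelled cells held 42.3, 47.4 and 39.3 M without cytokine and 41.6, 42.3 and 36.2 M with IL-33. Those of floxed-labelled cells held 48.7, 41.1 and 40.1 M without cytokine and 37.9, 33.8 and 35.8 M with IL-33. The first principal component held 32.1% of the variance and the second 22.4%.

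**Figure D1:**
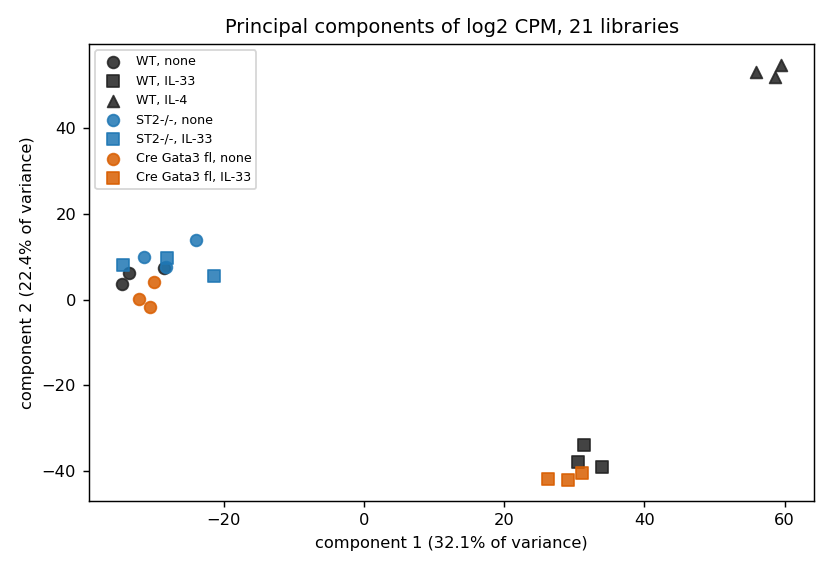
Principal components of log2 CPM, with 1 point per library, colour for the group and the share of variance on each axis (32.1% and 22.4%).

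The targeted genes were examined first. Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), which encodes the IL-33 receptor chain ST2, stood at 15.7 ± 1.45 CPM in unstimulated wild-type cells and 17.4 ± 2.95 CPM in unstimulated ST2KO-labelled cells (n = 3 each). With IL-33 the values were 15.7 ± 1.14 and 15.8 ± 2.51 CPM. Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034), a transcription factor of type 2 lymphocytes, was close to absent in every group. Its 3 libraries together held 17, 22 and 23 counts in wild-type cells without cytokine, with IL-33 and with IL-4, 4 and 4 in ST2KO-labelled cells, and 32 and 37 in floxed-labelled cells. Neither gene was lower in the libraries labelled as lacking it. Gene-level counts cannot see the loss of an exon, so these values did not check the deletions. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the chemokine receptor whose promoter drives the Cre, stood at 51.1 ± 1.80, 55.9 ± 4.98 and 63.4 ± 1.63 CPM in unstimulated wild-type, ST2KO-labelled and floxed-labelled cells. Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718) held 46 counts over the 3 IL-4 libraries and at most 4 over any other group, and was not tested.

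Sex separated the floxed-labelled libraries from all others. Xist, which is transcribed from the inactive X chromosome, stood at 277 to 376 CPM in all 6 floxed-labelled libraries and at no more than 0.0462 CPM in the other 15. The Y-linked gene Ddx3y stood at 61.0 to 86.3 CPM in those 15 libraries and had at most 1 count in each floxed-labelled library. Mitochondrially encoded transcripts made up 0.170 ± 0.0358%, 0.139 ± 0.0317% and 0.188 ± 0.0448% of counts in wild-type cells without cytokine, with IL-33 and with IL-4. The shares were 0.280 ± 0.0347% and 0.259 ± 0.0160% in ST2KO-labelled cells and 0.216 ± 0.0294% and 0.196 ± 0.0438% in floxed-labelled cells, without cytokine and with IL-33.

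The first comparison asked how wild-type macrophages responded to IL-33 (n = 3 against 3). IL-33 raised the arginase gene Arg1 969-fold, from 0.381 ± 0.125 to 373 ± 60.3 CPM, and raised 16 of 17 glycolytic, 21 of 22 cholesterol-synthesis and 13 of 18 inflammatory genes. Camera called the 3 lists, with adjusted p = 0.0724, 0.0485 and 0.062 in that order with an estimated correlation. Irg1, which encodes the enzyme that makes itaconate, rose 22.2-fold. The uncoupling protein gene Ucp2 did not pass (log2 change -0.09 ± 0.04, adjusted p = 0.0756), though it did with upper-quartile normalization (-0.14, 0.00940) and in a fit of only these groups (-0.10, 0.0474). In all, 5122 of 14473 genes were called, 2676 up and 2446 down, of which 606 rose and 367 fell by at least 2-fold. Upper-quartile normalization turned the split to 2251 up and 3010 down, or 42.8% up in place of 52.2%.

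Arg1 (chromosome 10, 24915221 to 24927484) changed by 9.92 ± 0.28 log2 units (adjusted p = 1.5e-16) and Irg1 (chromosome 14, 103046977 to 103056573) by 4.47 ± 0.29 (3.7e-11), from 3.30 to 73.1 CPM. Chil3, the chitinase-like protein Ym1 (chromosome 3, 106147554 to 106167564), rose 1.70-fold (0.76 ± 0.12, 2.1e-05), and Cx3cr1 fell 1.77-fold (-0.83 ± 0.11, 4.0e-06). Retnla, which encodes the secreted resistin-like molecule alpha (chromosome 16, 48842551 to 48844461), was called at an adjusted p of 0.00229 with a ratio of 19.2 (95% counting interval 6.24 to 95.7), on 3, 18 and 36 counts per library under IL-33. With limma-voom the Retnla call was lost (3.46, adjusted p = 0.0553). Il1rl1 (adjusted p = 0.97) and Gata3 (0.74) were not called. The largest rises included Serpinb2, a protease inhibitor of activated macrophages (chromosome 1, 107511423 to 107535478), at 2644-fold (counting interval 474 to 104469). The monocyte chemokine Ccl8 rose 571-fold to 61.3 CPM (2.4e-14), the acute-phase gene Saa3 461-fold to 266 CPM (1.4e-08), the matrix protease gene Mmp14 169-fold and the dicarboxylate transporter gene Slc13a3 127-fold. The cytokine gene Il1b (chromosome 2, 129364570 to 129371139) rose 70.1-fold (4.4e-10). Among falls, the Wnt antagonist gene Dkk2 (chromosome 3, 132085292 to 132180304) decreased by 15.8-fold, from 15.6 to 0.973 CPM (1.9e-13). Tox2 fell 12.3-fold, Cmah 12.0-fold, the lipoprotein lipase inhibitor gene Angptl4 8.76-fold and the prostaglandin-degrading enzyme gene Hpgd 5.89-fold (1.3e-09).

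Of the metabolic lists, glycolysis had 16 members up and 0 down of 17 measured (camera adjusted p = 8.4e-12), led by the glucose transporter Slc2a1 (2.64-fold), the lactate transporter Slc16a3 (2.63-fold) and Pfkfb3 (2.45-fold); adjusted p = 0.0724 with an estimated correlation. Cholesterol synthesis had 21 up and 0 down of 22 (5.7e-14, and 0.0485 with an estimated correlation), led by Idi1 (1.92-fold), Hsd17b7 (1.90-fold) and Mvd (1.89-fold). The nuclear-encoded respiratory chain had 35 up and 0 down of 65 (3.6e-08), with Cox5a at 1.53-fold; adjusted p = 0.23 with an estimated correlation. The TCA cycle had 11 up and 0 down of 20 (0.00024), with fumarase gene Fh1 at 1.68-fold; adjusted p = 0.0724 with an estimated correlation. Itaconate and Nrf2 targets had 10 up and 0 down of 14 (1.4e-05), led by the cystine transporter Slc7a11 (3.21-fold) and Nqo1 (2.67-fold); adjusted p = 0.0724 with an estimated correlation. Hypoxia genes had 12 up and 0 down of 15 (1.1e-07), led by Adm (9.41-fold) and P4ha2 (3.69-fold); adjusted p = 0.12 with an estimated correlation. The unfolded protein response had 10 up and 1 down of 17 (8.5e-05), with Pdia4 at 2.23-fold; adjusted p = 0.0867 with an estimated correlation. Not called were mitochondrially encoded mRNAs (0 up and 0 down of 12, adjusted p = 0.4), mitochondrial carriers (5 up and 1 down of 11, 0.1), mitochondrial biogenesis and mitophagy (5 up and 3 down of 17, 0.4, with the coactivator Ppargc1b up 2.94-fold) and fatty acid uptake and oxidation (4 up and 3 down of 18, 0.87).

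Alternative activation had 15 members up and 3 down of 20 (6.1e-06, and 0.00919 with an estimated correlation), with the lectin gene Mgl2 at 29.9-fold beside Arg1. Inflammatory cytokines had 13 up and 0 down of 18 (3.6e-08), among them Il1a at 153-fold and Ptgs2 at 12.3-fold; adjusted p = 0.062 with an estimated correlation. NF-kB targets had 14 up and 2 down of 18 (2.0e-06), with Sod2 at 3.30-fold; adjusted p = 0.062 with an estimated correlation. MHC class II had 8 up and 0 down of 8 (1.8e-05), with H2-DMb2 at 3.18-fold and Cd74 at 1.91-fold; adjusted p = 0.142 with an estimated correlation. Monocyte genes had 7 up and 0 down of 9 (1.3e-05, and 0.00804 with an estimated correlation), led by Hp (45.3-fold), Vcan (18.1-fold) and Fn1 (13.2-fold). Interferon-stimulated genes (0 up and 1 down of 22, 0.59), cell cycle (3 up and 3 down of 27, 0.94), cytokine receptors with GATA factors (6 up and 2 down of 16, 0.17), apoptotic cell clearance (6 up and 6 down of 17, 0.86), osteoclast genes (5 up and 3 down of 10, 0.38) and the macrophage core (5 up and 4 down of 12, 0.38) were not called. Within these, the IL-4 receptor chain gene Il4ra rose 4.51-fold and the receptor kinase gene Axl fell 2.77-fold.

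Markers of other cells also moved. Neutrophil genes had 9 up and 0 down of 12 (0.00013), with the collagenase gene Mmp8 at 16.1-fold; adjusted p = 0.0782 with an estimated correlation. Dendritic cell genes had 6 up and 0 down of 10 (0.047), with Zbtb46 at 5.36-fold; adjusted p = 0.156 with an estimated correlation. That call was also lost without unstimulated replicate 2 (0.0601) or IL-33 replicate 1 (0.0775). Erythroid and megakaryocyte genes had 3 up and 0 down of 4 (0.016), with the platelet chemokine gene Pf4 at 10.5-fold; adjusted p = 0.0724 with an estimated correlation. Mast cell and basophil (2 up and 1 down of 8, 0.57), eosinophil (1 up and 0 down of 3, 0.1), lymphocyte (2 up and 3 down of 11, 0.99) and stromal genes (1 up and 1 down of 6, 0.57) were not called as groups. The stem cell factor receptor gene Kit fell 4.68-fold and the type 2 cytokine gene Il13 rose at least 36.9-fold. Adjusted over the list alone, the counts differed from these only for inflammatory cytokines (14 up), interferon-stimulated genes (0 down), the TCA cycle (11 up and 1 down), the respiratory chain (36 up), carriers (5 up and 2 down), the unfolded protein response (11 up) and stromal genes (2 up). Bulk RNA does not tell whether a change lay in macrophages or in a minor cell population.

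**Figure D2:**
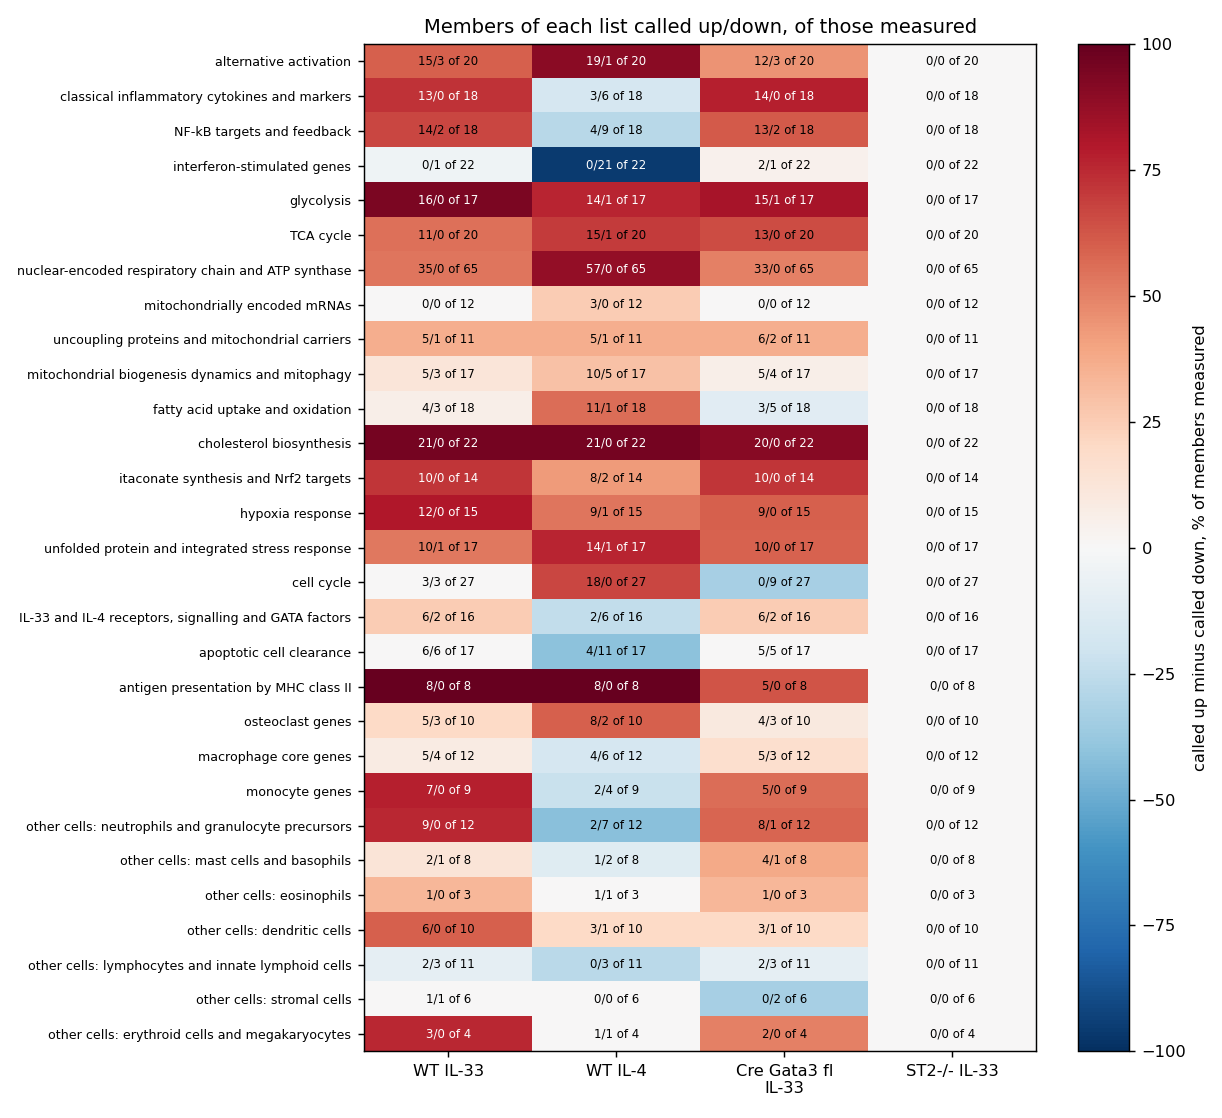
Members of the 29 gene lists called up and down, of those measured, for IL-33 and IL-4 in wild-type cells and IL-33 in floxed-labelled and ST2KO-labelled cells, with colour for the percentage up minus the percentage down. Cholesterol synthesis (21 of 22 members up) and glycolysis (16 of 17 up) rose with IL-33 in wild-type cells.

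The second comparison asked how wild-type macrophages responded to IL-4, the standard inducer of alternative activation (n = 3 against 3). IL-4 raised Arg1 3455-fold to 1332 CPM and Chil3 47.4-fold, lowered Cx3cr1 34.1-fold and lowered 21 of 22 interferon-stimulated genes, a list call that was lost at adjusted p = 0.3 with an estimated correlation. Il1rl1 rose 3.78-fold, from 15.7 ± 1.45 to 59.1 ± 8.59 CPM. In all, 6890 genes were called, 3627 up and 3263 down, with 838 rises and 762 falls of at least 2-fold. The split turned to 3209 up and 3718 down with upper-quartile normalization (46.3% up in place of 52.6%).

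Arg1 changed by 11.75 ± 0.29 log2 units (1.9e-18), Chil3 by 5.57 ± 0.12 (3.2e-19), Il1rl1 by 1.92 ± 0.14 (1.1e-10), Ucp2 by 0.31 ± 0.04 (8.9e-07) and Cx3cr1 by -5.09 ± 0.16 (6.6e-17). Retnla reached 713 CPM, a ratio of 27293 (counting interval 9339 to 132350, adjusted p = 4.8e-19). Irg1 (0.66 ± 0.31, adjusted p = 0.0851) and Gata3 (adjusted p = 0.696) were not called. Irg1 passed without unstimulated replicate 1 (0.89) or IL-4 replicate 3 (0.90) and without an expression filter (0.64). Of the largest rises, the ribonuclease gene Rnase2a (chromosome 14, 51255262 to 51256112) rose 20956-fold (counting interval 7170 to 101620), Tmem26 (chromosome 10, 68723646 to 68782650) 799-fold, Ear2 483-fold, and the STAT5 target and feedback inhibitor gene Cish (chromosome 9, 107296026 to 107302784) 151-fold. The E-cadherin gene Cdh1 rose 129-fold. The largest falls included Ifit3b (21.1-fold), Adgre4 (20.2-fold), Cmah (18.1-fold), Hpgd (15.8-fold) and the purinergic-type receptor gene Gpr34 (14.6-fold).

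Alternative activation had 19 members up and 1 down of 20 (1.1e-13, and 0.000162 with an estimated correlation). The respiratory chain had 57 up and 0 down of 65 (2.1e-15), with the ATP synthase gene Atp5b at 1.87-fold; adjusted p = 0.131 with an estimated correlation. The TCA cycle had 15 up and 1 down of 20 (1.3e-06, and 0.0408 with an estimated correlation), led by Idh3a (2.27-fold). Glycolysis had 14 up and 1 down of 17 (9.1e-07), with Pfkp at 2.85-fold; adjusted p = 0.216 with an estimated correlation. Cholesterol synthesis had 21 up and 0 down of 22 (2.9e-09), with Sqle at 1.90-fold; adjusted p = 0.115 with an estimated correlation. Fatty acid uptake and oxidation had 11 up and 1 down of 18 (0.00088), with the fatty acid receptor gene Cd36 at 4.73-fold and Fabp4 at 3.90-fold; adjusted p = 0.119 with an estimated correlation. Interferon-stimulated genes had 0 up and 21 down of 22 (3.8e-08), with Ifit3 down 12.4-fold and Irf7 down 5.52-fold; adjusted p = 0.3 with an estimated correlation. Cell cycle had 18 up and 0 down of 27 (8.1e-05), with Rrm2 at 2.34-fold; adjusted p = 0.419 with an estimated correlation. The unfolded protein response had 14 up and 1 down of 17 (1.2e-06), with Chac1 at 7.43-fold; adjusted p = 0.0815 with an estimated correlation. MHC class II had 8 up and 0 down of 8 (3.0e-07), with Cd74 at 3.76-fold; adjusted p = 0.119 with an estimated correlation.

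Osteoclast genes had 8 up and 2 down of 10 (0.00011, and 0.0408 with an estimated correlation), with the fusion gene Ocstamp at 90.4-fold and Car2 at 39.8-fold. Apoptotic cell clearance had 4 up and 11 down of 17 (0.01), with the scavenger receptor gene Stab1 down 4.10-fold; adjusted p = 0.185 with an estimated correlation. Itaconate and Nrf2 targets had 8 up and 2 down of 14 (0.012), with Slc7a11 at 5.33-fold; adjusted p = 0.3 with an estimated correlation. Hypoxia genes had 9 up and 1 down of 15 (0.0094), with Bhlhe40 at 8.28-fold; adjusted p = 0.419 with an estimated correlation. Inflammatory cytokines had 3 up and 6 down of 18 and were not called as a group (adjusted p = 0.44), with Cxcl1 down 14.9-fold, Cxcl10 down 13.3-fold and Ccl2 up 4.88-fold. The macrophage core (4 up and 6 down of 12) was not called at an adjusted p of 0.0516, but was in all 6 fits with 1 library left out (0.0307 to 0.0446). Carriers (5 up and 1 down of 11, 0.0516) were called without replicate 3 unstimulated (0.0482) or with IL-4 (0.0357). Among lists of other cells none was called, while the dendritic cell markers Itgax (15.5-fold) and Zbtb46 (13.5-fold) rose. Adjusted over the list alone, the counts of the lists named here differed only for glycolysis (15 up), the respiratory chain (60 up), fatty acid genes (13 up) and cell cycle (20 up).

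Direct comparison of IL-33 with IL-4 in wild-type cells asked which genes the cytokines set to different levels (n = 3 against 3). IL-33 left 16 of 18 inflammatory and 21 of 22 interferon-stimulated genes higher, and IL-4 left 15 of 20 alternative-activation, 36 of 65 respiratory-chain and 20 of 27 cell-cycle genes higher. Of these lists only alternative activation was still called with an estimated correlation (adjusted p = 0.000506, against 0.0624, 0.262, 0.253 and 0.356 for the others in that order). Arg1 was 3.57-fold lower under IL-33 than under IL-4, and Irg1 14.1-fold higher. In all, 5772 genes differed, 2772 higher and 3000 lower under IL-33, with 777 and 628 of these by at least 2-fold.

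The differences were -1.84 ± 0.16 log2 units for Arg1 (3.2e-09), 3.82 ± 0.27 for Irg1 (1.0e-10), -4.80 ± 0.12 for Chil3 (2.5e-18), -10.47 ± 0.25 for Retnla (2.3e-18), 4.27 ± 0.16 for Cx3cr1 (3.0e-15), -1.91 ± 0.14 for Il1rl1 (1.4e-10) and -0.41 ± 0.04 for Ucp2 (2.2e-08). Gata3 did not pass (adjusted p = 0.99). Genes higher under IL-33 included Saa3 (468-fold), Serpinb2 (428-fold), Il1b (175-fold) and the ferroxidase gene Cp (115-fold). Genes lower under IL-33 included Rnase2a (534-fold), Tmem26 (115-fold) and Cldn11 (100.1-fold).

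Inflammatory cytokines had 16 members higher and 0 lower of 18 (1.9e-07), with the chemokine gene Cxcl1 at 172-fold; adjusted p = 0.0624 with an estimated correlation. NF-kB targets had 13 higher and 3 lower of 18 (6.8e-06), with Nfkbiz at 10.99-fold; adjusted p = 0.0624 with an estimated correlation. Interferon-stimulated genes had 21 higher and 1 lower of 22 (1.5e-08), with Ifit3 at 6.02-fold; adjusted p = 0.262 with an estimated correlation. Monocyte genes had 7 higher and 1 lower of 9 (0.0001, and 0.01 with an estimated correlation), with F13a1 at 19.9-fold. Alternative activation had 2 higher and 15 lower of 20 (8.9e-11, and 0.000506 with an estimated correlation), with the VEGF receptor gene Flt1 22.0-fold lower. The respiratory chain had 0 higher and 36 lower of 65 (1.6e-07), with Cyc1 1.49-fold lower; adjusted p = 0.253 with an estimated correlation. The TCA cycle had 2 higher and 13 lower of 20 (0.0047), with Idh3a 1.65-fold lower; adjusted p = 0.131 with an estimated correlation. Fatty acid genes had 1 higher and 11 lower of 18 (0.0001), with Fabp4 3.50-fold lower; adjusted p = 0.0624 with an estimated correlation. Cell cycle had 0 higher and 20 lower of 27 (6.8e-06), with Pcna 2.14-fold lower; adjusted p = 0.356 with an estimated correlation. Glycolysis was not called (5 higher and 2 lower of 17, adjusted p = 0.3), nor was cholesterol synthesis (5 higher and 2 lower of 22, 0.51). When calls were adjusted over the list alone, the counts differed for NF-kB targets (4 lower), the respiratory chain (1 higher and 42 lower), cell cycle (23 lower), neutrophil genes (10 higher), mitochondrially encoded mRNAs (9 lower), hypoxia (8 higher), MHC class II (1 higher) and the unfolded protein response (12 lower).

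Lists of other cells were called as well. Neutrophil genes had 9 higher and 0 lower of 12 (2.4e-05), with Mmp8 at 11.7-fold; adjusted p = 0.0624 with an estimated correlation. Lymphocyte genes had 5 higher and 0 lower of 11 (0.046), with Il13 at least 37.1-fold higher; adjusted p = 0.131 with an estimated correlation. That call was lost with RLE factors (0.0527), without IL-33 replicate 2 (0.0713) and without IL-4 replicate 1 (0.0903) or 2 (0.0750). Erythroid and megakaryocyte genes had 2 higher and 0 lower of 4 (0.02), with Pf4 at 15.8-fold; adjusted p = 0.0896 with an estimated correlation, and 0.0599 without IL-33 replicate 3. Mitochondrially encoded mRNAs had 0 higher and 7 lower of 12 (0.027); adjusted p = 0.53 with an estimated correlation. They were not called without IL-33 replicate 2 (0.0760) or without IL-4 replicate 1 (0.0702) or 2 (0.0752).

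Higher lists further included cytokine receptors with GATA factors (8 higher and 4 lower of 16, 0.012, and 0.0988 with an estimated correlation), with Il4ra at 6.43-fold, and the macrophage core (7 higher and 4 lower of 12, 0.012, and 0.0896 with an estimated correlation), with the Fc receptor gene Fcgr1 at 10.7-fold. Hypoxia (7 higher and 1 lower of 15, 0.018, and 0.496 with an estimated correlation) and apoptotic cell clearance (8 higher and 3 lower of 17, 0.026, and 0.206 with an estimated correlation) were also higher, with Stab1 at 4.55-fold. Lower lists further included MHC class II (0 higher and 7 lower of 8, 0.00019, and 0.2 with an estimated correlation), osteoclast genes (3 higher and 7 lower of 10, 0.00026, and 0.0569 with an estimated correlation) and the unfolded protein response (1 higher and 11 lower of 17, 0.0016, and 0.161 with an estimated correlation), with Ocstamp 47.2-fold and Phgdh 3.26-fold lower.

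The responses to the cytokines shared 3113 genes that moved in the same direction. Of these, 1654 rose with both (671 if the responses were independent) and 1459 fell with both (551 if independent), while 556 moved in opposite directions (1216 if independent). Both responses were measured against the same 3 unstimulated libraries, which by itself makes changes alike. In 50 simulations of unchanged genes with shared controls, the mean correlation of the changes was 0.499 (range 0.453 to 0.538) and 0 genes were called in both. The real correlation across genes was 0.479, and the covariance was 0.398 against 0.0585 in the simulations. Part of the excess of shared calls may come from the shared controls, by an amount that was not measured.

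**Figure D3:**
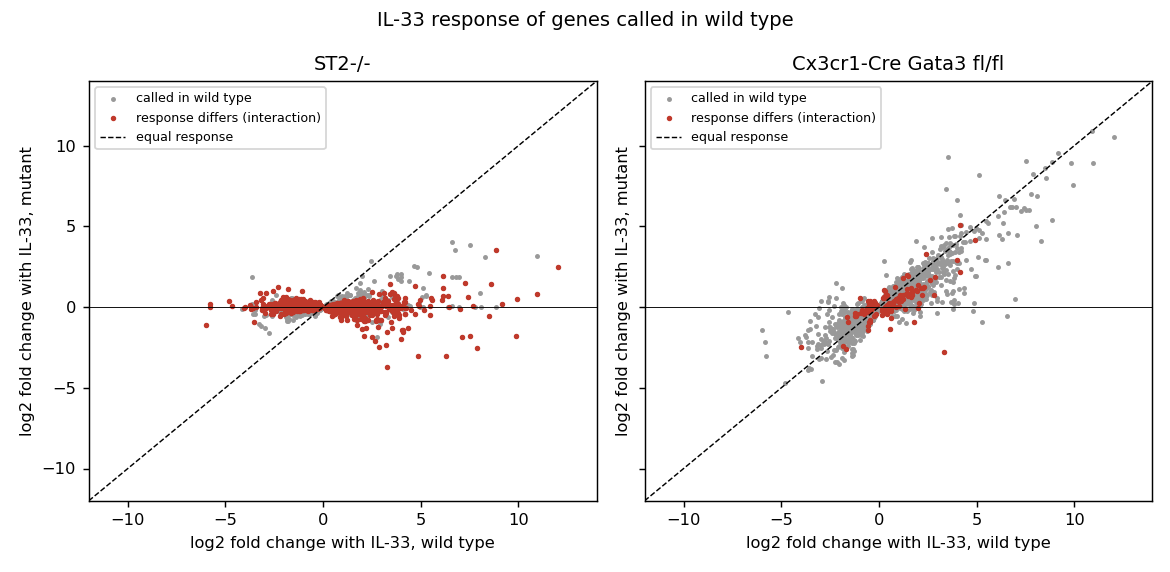
Log2 change with IL-33 in ST2KO-labelled cells (left) and floxed-labelled cells (right) against that in wild-type cells, with 1 point for each of the 5122 genes called in the wild type, red where the interaction was called and a dashed line for equal responses. Over all tested genes the correlation with the wild-type response was 0.0853 for ST2KO-labelled and 0.729 for floxed-labelled cells.

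The response to IL-33 in ST2KO-labelled cells asked whether the response needed the receptor (n = 3 against 3). No gene was called with edgeR, 507 genes were under an unadjusted p of 0.05 where 724 would be reached by chance, and the smallest adjusted p was 0.671. DESeq2 also called 0 genes (546 at the unadjusted level), limma-voom called 0 (572), and edgeR without an expression filter called 70. Arg1 stood at 0.51 CPM without and 0.74 CPM with IL-33 (0.52 ± 0.48, adjusted p = 1), Irg1 at 3.66 and 3.16, Chil3 at 8.21 and 6.51, and Ucp2 at 1019 and 1029. Cx3cr1 (-0.11) and Il1rl1 (-0.14) were not called either. No member of any list was called. Camera called cholesterol synthesis up (median log2 change 0.10, 3.9e-07) and the respiratory chain down (median -0.04, 0.00046). With an estimated correlation both were lost, at an adjusted p of 0.921 each. Cholesterol synthesis was also lost without IL-33 replicate 2 (0.119), and the respiratory chain without unstimulated replicate 2 (0.606) or IL-33 replicate 3 (0.941). Other lists were called only with a library left out. They were cell cycle (adjusted p = 0.0914 with all libraries) without unstimulated replicate 1 (0.0183) or 3 (0.000407) or IL-33 replicate 2 (3.2e-09), and mitochondrially encoded mRNAs (0.0914) without replicate 3 unstimulated (0.000925) or with IL-33 (0.0460). Interferon-stimulated genes (0.994) were called without unstimulated replicate 1 (0.00107) or 2 (1.0e-05) or IL-33 replicate 2 (0.0140), glycolysis (0.808) and hypoxia (0.811) without IL-33 replicate 2 (1.5e-06 and 0.00552), and inflammatory cytokines (0.559) without IL-33 replicate 3 (0.0460). Chil3 was called without an expression filter (-0.34).

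Whether the ST2KO-labelled response differed from that of the wild type was tested as an interaction (n = 3 in each of 4 groups). It called 3284 genes, 1539 with a higher and 1745 with a lower log2 response in ST2KO-labelled cells, and 755 of these differed by at least 2-fold. Under upper-quartile normalization 1841 were higher and 1500 lower, or 55.1% higher in place of 46.9%. The Arg1 response was lower (-9.40 ± 0.76 log2 units, 5.8e-09), the Irg1 response was -4.68 ± 0.42 relative to wild type (3.0e-08) and the Chil3 response -1.09 ± 0.17 (5.5e-05). The loss of Cx3cr1 was smaller by 0.71 ± 0.16 (0.00176). Serpinb2 (-10.10 ± 1.46), Ccl8 (-8.96 ± 1.303), Slc13a3 (-7.14 ± 0.63) and Mmp14 (-6.80 ± 0.93) lost their rises, and Dkk2 (3.997 ± 0.234), Tox2 (3.58 ± 0.25), Cmah (3.55 ± 0.26) and Angptl4 (2.97 ± 0.25) lost their falls. Ucp2 (adjusted p = 0.192), Il1rl1 (0.653), Gata3 (0.934) and Retnla (0.0582) did not pass. Retnla passed without wild-type IL-33 replicate 3 (-4.67), without ST2KO-labelled replicate 1 of either treatment (-4.76 unstimulated, -5.14 with IL-33) and without an expression filter (-4.22). Of the genes that rose with IL-33 in wild-type cells, 55.6% had the same sign in ST2KO-labelled cells and 0 were called there, and of those that fell, 48.9% and 0.

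Glycolysis had 0 members with a higher and 15 with a lower response of 17 (3.2e-12), with Slc2a1 at -1.45; adjusted p = 0.0679 with an estimated correlation. Cholesterol synthesis had 0 higher and 18 lower of 22 (2.6e-11), with Mvd at -0.82; adjusted p = 0.0615 with an estimated correlation. The respiratory chain had 0 higher and 32 lower of 65 (2.6e-10), with Cox5a at -0.63; adjusted p = 0.155 with an estimated correlation. Inflammatory cytokines had 0 higher and 10 lower of 18 (1.1e-06), with Il1b at -4.21; adjusted p = 0.0679 with an estimated correlation. Alternative activation had 2 higher and 13 lower of 20 (1.2e-05, and 0.0115 with an estimated correlation), with Mgl2 at -4.84 ± 0.19. Monocyte genes had 0 higher and 7 lower of 9 (2.2e-05, and 0.0109 with an estimated correlation), with Hp at -4.91. When calls were adjusted over the list alone, the counts were 19 lower for cholesterol synthesis, 35 lower for the respiratory chain, 11 lower for inflammatory cytokines and 3 higher with 15 lower for alternative activation.

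Lower responses in ST2KO-labelled cells were also called for NF-kB targets (2 higher and 13 lower of 18, 1.0e-06, and 0.0615 with an estimated correlation), the TCA cycle (0 higher and 7 lower of 20, 0.00051, and 0.0679 with an estimated correlation), itaconate and Nrf2 targets (0 higher and 9 lower of 14, 1.6e-05, and 0.0679 with an estimated correlation) and hypoxia (0 higher and 11 lower of 15, 1.5e-07, and 0.104 with an estimated correlation). The unfolded protein response (0 higher and 8 lower of 17, 4.7e-05, and 0.0747 with an estimated correlation) and MHC class II (0 higher and 7 lower of 8, 1.4e-05, and 0.113 with an estimated correlation) behaved alike, with Cd74 at -0.99. Of other cells, neutrophil genes (0 higher and 8 lower of 12, 7.2e-05, and 0.0679 with an estimated correlation), eosinophil genes (0 higher and 2 lower of 3, 0.02, and 0.0839 with an estimated correlation), dendritic cell genes (0 higher and 5 lower of 10, 0.014, and 0.0851 with an estimated correlation) and erythroid and megakaryocyte genes (0 higher and 3 lower of 4, 0.0047, and 0.0615 with an estimated correlation) were called, with Mmp8 at -4.06 and Pf4 at -3.32. For the TCA cycle, Nrf2 targets and the unfolded protein response, 8, 10 and 9 members were lower when adjusted over the list alone.

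The response to IL-33 in floxed-labelled cells asked how far the response was kept under the Gata3 label (n = 3 against 3). Most of it was present, but Arg1 reached only 44.3 ± 3.69 CPM, against 373 ± 60.3 CPM in the wild type. Irg1 rose 25.1-fold, 15 of 17 glycolytic and 20 of 22 cholesterol-synthesis genes rose, and Il1rl1 itself fell 2.27-fold. Of these lists glycolysis was lost at adjusted p = 0.0907 with an estimated correlation. In all, 4835 genes were called, 2471 up and 2364 down, with 501 rises and 416 falls of at least 2-fold. With upper-quartile normalization the split moved to 2001 up and 2985 down, or 40.1% up in place of 51.1%.

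Arg1 changed by 7.58 ± 0.31 log2 units (4.6e-14), Irg1 by 4.65 ± 0.29 (4.1e-11), Chil3 by 0.71 ± 0.11 (1.8e-05), Cx3cr1 by -1.41 ± 0.11 (2.3e-09), Il1rl1 by -1.18 ± 0.15 (1.8e-06) and Ucp2 by -0.19 ± 0.04 (0.000899). Retnla (adjusted p = 0.0723) and Gata3 (0.593) were not called, although Retnla was without unstimulated floxed-labelled replicate 3 (6.15) or without an expression filter (2.72). Serpinb2 rose 2768-fold (counting interval 496 to 109383), Ccl8 851-fold (counting interval 291 to 4129) and Saa3 510-fold to 102 CPM. Tox2 fell 14.8-fold, Cmah 13.6-fold, the receptor gene Cd300e 8.88-fold and Samd4 6.57-fold.

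Glycolysis had 15 members up and 1 down of 17 (4.9e-11), with Slc2a1 at 2.41-fold; adjusted p = 0.0907 with an estimated correlation. Cholesterol synthesis had 20 up and 0 down of 22 (2.0e-16, and 0.0416 with an estimated correlation), with Mvd at 2.34-fold. The TCA cycle had 13 up and 0 down of 20 (3.7e-05, and 0.0479 with an estimated correlation). The respiratory chain had 33 up and 0 down of 65 (2.4e-07), with Cox5a at 1.46-fold; adjusted p = 0.273 with an estimated correlation. Itaconate and Nrf2 targets had 10 up and 0 down of 14 (2.4e-07, and 0.0479 with an estimated correlation), with Gclm at 2.83-fold. Inflammatory cytokines had 14 up and 0 down of 18 (2.4e-07), with Il1b at 116-fold; adjusted p = 0.0593 with an estimated correlation. Alternative activation had 12 up and 3 down of 20 (0.00033, and 0.0425 with an estimated correlation), with Mgl2 at 18.1-fold. Cell cycle had 0 up and 9 down of 27 (0.013), with Ccnb2 1.73-fold lower; adjusted p = 0.605 with an estimated correlation. That call was also lost without replicate 2 of either treatment (0.0703 unstimulated, 0.106 with IL-33). Monocyte genes had 5 up and 0 down of 9 (0.00022, and 0.0322 with an estimated correlation), with Vcan at 24.5-fold. Adjusted over the list alone, the counts were 15 up for alternative activation, 21 up for cholesterol synthesis, 14 up for the TCA cycle and 35 up for the respiratory chain.

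NF-kB targets (13 up and 2 down of 18, 8.6e-06, and 0.0629 with an estimated correlation), hypoxia (9 up and 0 down of 15, 0.0001, and 0.273 with an estimated correlation) and the unfolded protein response (10 up and 0 down of 17, 0.0001, and 0.0923 with an estimated correlation) were called too, with Bcl3 at 3.05-fold and Ero1l at 2.32-fold. MHC class II had 5 up and 0 down of 8 (0.031, and 0.426 with an estimated correlation), and was lost without replicate 2 of either treatment (0.0611 unstimulated, 0.106 with IL-33). Neutrophil genes had 8 up and 1 down of 12 (0.00021, and 0.0923 with an estimated correlation), with Mmp8 at 12.7-fold (9 up when adjusted over the list alone). Erythroid and megakaryocyte genes had 2 up and 0 down of 4 (0.036, and 0.105 with an estimated correlation), with Pf4 at 6.48-fold. That call was lost without unstimulated replicate 1 (0.0751), 2 (0.0703) or 3 (0.0783) and without IL-33 replicate 1 (0.0675) or 2 (0.0850).

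The interaction of the floxed label with IL-33 called 176 genes, 78 with a higher and 98 with a lower log2 response than in wild-type cells (n = 3 in each of 4 groups). The Arg1 response differed by -2.34 ± 0.79 log2 units and was not called (adjusted p = 0.171), but passed without an expression filter (-2.34). The Il1rl1 response was lower (-1.19 ± 0.21, 0.00405), Dkk2 fell less (1.48 ± 0.25, 0.00284) and the tumour suppressor candidate gene Tusc1 had a higher response (0.99 ± 0.19, 0.0121). Lower responses were found for Tmem26 (-2.05 ± 0.30, 0.000792), the lectin receptor gene Clec4b1 (-1.91 ± 0.30, 0.00142), the ergothioneine transporter gene Slc22a4 (-1.79 ± 0.29, 0.00229) and the eotaxin receptor gene Ccr3 (-1.43 ± 0.22, 0.001). Irg1 (adjusted p = 0.906), Ucp2 (0.509), Chil3 (0.93), Cx3cr1 (0.0774), Gata3 (0.974) and Retnla (0.849) did not pass. Cx3cr1 passed with DESeq2 (-0.57), with limma-voom (-0.58), without a filter (-0.59) and without floxed-labelled IL-33 replicate 1 (-0.75). Of 2676 genes raised by IL-33 in wild-type cells, 95.3% had the same sign in floxed-labelled cells, 1855 were called there too, and 73 had a smaller and 15 a larger response by this test. Of 2446 genes lowered in wild-type cells, 93.6% had the same sign, 1572 were called, and 50 had a smaller and 10 a larger response. For the 606 genes raised at least 2-fold, the median change was 1.89 log2 units in wild-type and 1.39 in floxed-labelled cells.

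Camera called lower responses in floxed-labelled cells for MHC class II (0 higher and 1 lower of 8, 4.9e-05), hypoxia (0 higher and 1 lower of 15, 0.00018), cell cycle (0 higher and 0 lower of 27, 0.00036) and alternative activation (0 higher and 1 lower of 20, 0.043). These calls were lost when the correlation was estimated, at an adjusted p of 0.434, 0.487, 0.726 and 0.434 in that order. Cell cycle was also lost without wild-type IL-33 replicate 1 (0.107), and alternative activation without that library (0.0743), without unstimulated wild-type replicate 1 (0.0908) or without floxed-labelled IL-33 replicate 2 (0.0536). Stromal genes (0 higher and 0 lower of 6) were not called at an adjusted p of 0.0943, but were called lower in 11 of 12 fits with 1 library left out (0.00253 to 0.0443), all but that without unstimulated floxed-labelled replicate 1. Glycolysis (0.149) was called without unstimulated wild-type replicate 2 (0.0425) or unstimulated floxed-labelled replicate 3 (0.0463), and mitochondrially encoded mRNAs (0.325) without unstimulated wild-type replicate 3 (0.0188). Neutrophil genes (0.149) were called without floxed-labelled IL-33 replicate 2 (0.0369) or 3 (0.0397), and the respiratory chain (0.330) without the latter (0.0211). With p-values adjusted over the list alone, 6 members of MHC class II, 2 of hypoxia and 7 of alternative activation had a lower response. The count of 176 moved between 52 and 273 when 1 library was left out.

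Unstimulated ST2KO-labelled cells were compared with unstimulated wild-type cells to see what differed before any cytokine (n = 3 against 3). The 196 called genes, 126 up and 70 down, included neighbours of Il1rl1 on chromosome 1. The IL-1 receptor gene Il1r1 (chromosome 1, 40225080 to 40317257) rose 45.4-fold, from 0.682 to 30.6 CPM (5.50 ± 0.29, 1.1e-10), and the IL-36 receptor gene Il1rl2 (40324610 to 40367562) 4.03-fold (2.01 ± 0.16, 1.1e-07). The IL-18 receptor accessory gene Il18rap (40515362 to 40551705) fell 3.76-fold (-1.91 ± 0.16, 1.1e-07), the adaptor gene Nck2 (43444579 to 43570515) 3.08-fold (-1.62 ± 0.11, 7.4e-09) and Creg2 (39618406 to 39651474) 3.07-fold (-1.62 ± 0.16, 2.0e-06). Cnbd2 fell 2.55-fold (-1.35 ± 0.12, 2.0e-07). In all, 8 of the 92 genes tested within 10 Mb of Il1rl1 were called. None of Il1rl1 (adjusted p = 0.658), Gata3 (0.262), Cx3cr1 (0.641), Ucp2 (0.325), Irg1 (0.876), Arg1 (0.773), Chil3 (0.949) and Retnla (0.581) was called. The response of Il1rl2 to IL-33 (-3.63 ± 0.22, 6.5e-11) and that of Il1r1 (-2.22 ± 0.39, 0.000182) were lower than in wild-type cells, where IL-33 had raised them 11.1-fold and 5.07-fold.

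**Figure D4:**
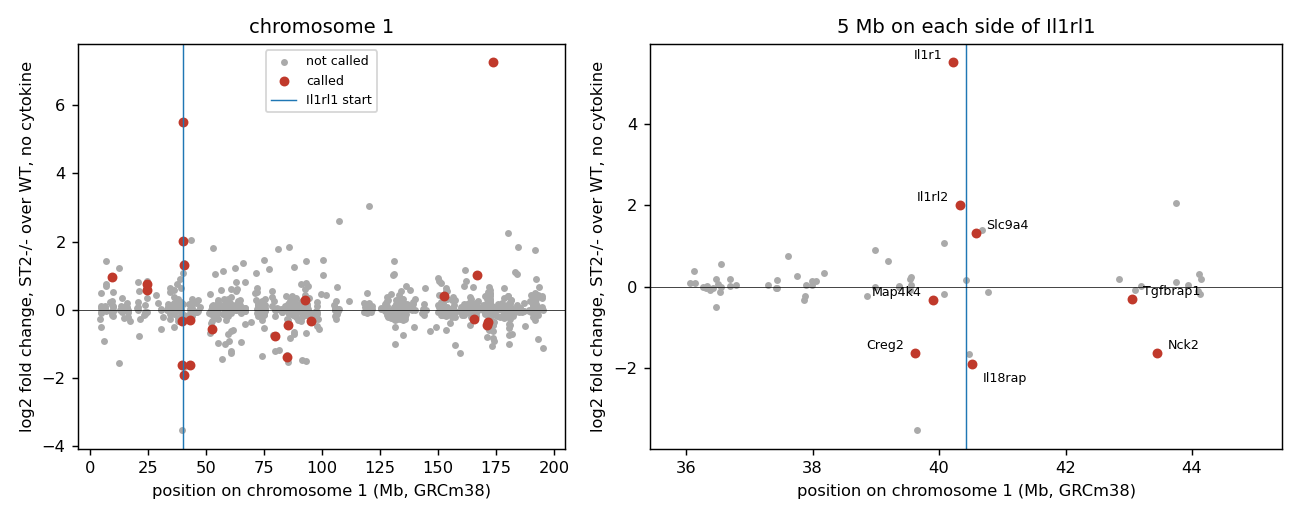
Log2 difference between unstimulated ST2KO-labelled and wild-type cells for tested genes along chromosome 1 and within 5 Mb of Il1rl1, with 1 point per gene and called genes marked. Il1r1 (5.50) and Il1rl2 (2.01) lay above and Il18rap (-1.91) below 0.

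Interferon-stimulated genes were lower as a group (0 up and 1 down of 22, camera adjusted p = 3.9e-18, median log2 difference -0.68); adjusted p = 0.292 with an estimated correlation. Mitochondrially encoded mRNAs were higher (5 up and 0 down of 12, 1.2e-13, median 0.76); adjusted p = 0.292 with an estimated correlation. Cell cycle was higher (2 up and 0 down of 27, 2.4e-11); adjusted p = 0.306 with an estimated correlation. Cholesterol synthesis was higher (1 up and 0 down of 22, 6.8e-08); adjusted p = 0.292 with an estimated correlation. With p-values adjusted over the list alone, 22 interferon-stimulated genes were lower, and 10 mitochondrially encoded, 16 cell-cycle and 6 cholesterol-synthesis genes were higher.

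Further lists were called in these cells. MHC class II was higher (0 up and 0 down of 8, 3.1e-05, and 0.295 with an estimated correlation). NF-kB targets were higher (1 up and 0 down of 18, 0.0062, and 0.306 with an estimated correlation) except without wild-type replicate 1 (0.0894). The respiratory chain was higher (2 up and 0 down of 65, 0.014, and 0.659 with an estimated correlation) except without wild-type replicate 1 (0.129) or ST2KO-labelled replicate 2 (0.579). Hypoxia was higher (0 up and 0 down of 15, 0.032, and 0.63 with an estimated correlation) and apoptotic cell clearance lower (0 up and 1 down of 17, 0.038, and 0.306 with an estimated correlation). Both calls were lost without wild-type replicate 1 (0.146 and 0.199), wild-type replicate 3 (0.124 and 0.0769) or ST2KO-labelled replicate 2 (0.401 and 0.290). Of other cells, eosinophil genes (0 up and 0 down of 3, 0.038, and 0.292 with an estimated correlation) and dendritic cell genes (1 up and 0 down of 10, 0.037, and 0.292 with an estimated correlation) were higher. The eosinophil call was lost without wild-type replicate 1 (0.129) or ST2KO-labelled replicate 2 (0.186), and the dendritic cell call without wild-type replicate 2 (0.0772) or ST2KO-labelled replicate 2 (0.0784) or 3 (0.0852). Glycolysis (0.303) was called only without ST2KO-labelled replicate 3 (0.0260). Members up when adjusted over the list alone were 4 for MHC class II, 3 for NF-kB targets, 3 for the respiratory chain, 1 for hypoxia and 2 for dendritic cells. The count of 196 fell to 64 and 54 without wild-type replicate 1 or 3 and to 65 and 98 without ST2KO-labelled replicate 2 or 3.

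Unstimulated floxed-labelled cells were compared with unstimulated wild-type cells in the same way (n = 3 against 3), and sex differed completely between these groups. The 1425 called genes, 810 up and 615 down, included 1364 on autosomes. Slc22a4 rose 36.5-fold, from 1.04 to 37.8 CPM (5.19 ± 0.22, 1.7e-13), the growth factor gene Gdf3 5.30-fold (2.41 ± 0.07, 2.5e-16), Tmem26 3.22-fold and Chil3 1.86-fold (0.90 ± 0.12, 3.7e-05). Eps8l1 fell 3.35-fold (4.2e-10). The Y-linked genes Ddx3y (at least 928-fold), Eif2s3y (at least 859-fold), Kdm5d (at least 612-fold) and Uty (at least 524-fold) were lower. Il1rl1 (adjusted p = 0.747), Gata3 (0.585), Cx3cr1 (0.0763), Ucp2 (0.0819), Irg1 (0.322), Arg1 (0.574) and Retnla (0.968) were not called. Cx3cr1 passed with DESeq2 (0.30), with limma-voom (0.31), in a fit of only these groups (0.31) and without a filter (0.31), as did Irg1 without a filter (-0.57).

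Cell cycle had 18 members up and 0 down of 27 (2.7e-18), with Rrm2 at 1.83-fold and Mki67 at 1.68-fold; adjusted p = 0.221 with an estimated correlation. MHC class II had 7 up and 0 down of 8 (6.8e-13), with H2-Aa at 2.43-fold and H2-Eb1 at 2.06-fold; adjusted p = 0.0583 with an estimated correlation. Interferon-stimulated genes had 0 up and 6 down of 22 (3.3e-10), with Bst2 down 1.66-fold; adjusted p = 0.525 with an estimated correlation. Neutrophil genes had 6 up and 0 down of 12 (8.3e-07), with the granule gene Mpo at 2.35-fold and S100a9 at 2.05-fold; adjusted p = 0.0583 with an estimated correlation. Stromal genes had 3 up and 0 down of 6 (0.004), with Col1a2 at least 12.6-fold higher; adjusted p = 0.0583 with an estimated correlation. Fatty acid genes had 4 up and 0 down of 18 (0.033, and 0.525 with an estimated correlation), a call lost without wild-type replicate 1 (0.108) or floxed-labelled replicate 1 (0.0530) or 2 (0.0673). Mitochondrially encoded mRNAs had 2 up and 0 down of 12 (0.0089, and 0.685 with an estimated correlation), a call lost without wild-type replicate 3 (0.247) or floxed-labelled replicate 3 (0.0689). Called only with a library left out were the TCA cycle (0.0714) without wild-type replicate 1 (0.0316) or 3 (0.0420) or floxed-labelled replicate 3 (0.0492), glycolysis (0.162) without wild-type replicate 1 (0.0396) or floxed-labelled replicate 2 (0.0172), and hypoxia (0.199) without wild-type replicate 2 (0.0282). When calls were adjusted over the list alone, the counts were 26 up for cell cycle, 15 down for interferon-stimulated genes, 8 up for neutrophil genes and 6 up for mitochondrially encoded mRNAs. The count of 1425 fell to 784 and 810 without wild-type replicate 1 or 3 and to 658 without floxed-labelled replicate 2, and genotype could not be separated from sex.

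Levels under IL-33 in floxed-labelled and wild-type cells, which differed in sex, were compared after the data had been seen (n = 3 against 3). Arg1 was 8.43-fold lower in floxed-labelled cells (-3.07 ± 0.17, 3.8e-11), Mgl2 2.01-fold lower and Il1rl1 2.44-fold lower (-1.29 ± 0.15, 4.5e-06), while Chil3 was 1.79-fold higher (0.84 ± 0.11, 1.7e-05). Irg1 (adjusted p = 0.303), Ucp2 (0.819), Cx3cr1 (0.15), Retnla (0.263) and Gata3 (0.473) did not pass. Without a filter Irg1 (-0.40), Cx3cr1 (-0.27) and Retnla (-1.18) passed, and Cx3cr1 also did without floxed-labelled IL-33 replicate 1 (-0.44). Slc22a4 (10.5-fold), the deiodinase gene Dio2 (5.69-fold), Gdf3 (5.08-fold) and Dkk2 (3.84-fold) were higher, and Msx3 was 8.86-fold lower beside the Y-linked genes. In all, 1642 genes differed, 796 higher and 846 lower. Alternative activation had 3 members higher and 8 lower of 20 (0.00061), with Flt1 3.01-fold and Cdh1 2.47-fold lower; adjusted p = 0.139 with an estimated correlation. Interferon-stimulated genes had 0 higher and 9 lower of 22 (2.3e-07); adjusted p = 0.443 with an estimated correlation. Cell cycle had 7 higher and 0 lower of 27 (1.7e-06); adjusted p = 0.443 with an estimated correlation. Lower lists further included inflammatory cytokines (0 higher and 3 lower of 18, 0.00054, and 0.324 with an estimated correlation), glycolysis (0 higher and 3 lower of 17, 0.00032, and 0.443 with an estimated correlation) and hypoxia (0 higher and 2 lower of 15, 0.008, and 0.528 with an estimated correlation). Higher lists included MHC class II (5 higher and 0 lower of 8, 4.2e-05, and 0.324 with an estimated correlation), neutrophil genes (5 higher and 0 lower of 12, 3.6e-05, and 0.199 with an estimated correlation), mitochondrially encoded mRNAs (4 higher and 0 lower of 12, 0.00014, and 0.443 with an estimated correlation) and mast cell and basophil genes (1 higher and 0 lower of 8, 0.0077, and 0.22 with an estimated correlation). Members lower when adjusted over the list alone were 13 for interferon-stimulated genes, 4 for inflammatory cytokines, 7 for glycolysis and 3 for hypoxia, and members higher were 13 for cell cycle, 7 for MHC class II, 8 for neutrophils, 6 for mitochondrially encoded mRNAs and 2 for mast cells and basophils. Not called with all libraries, but called without 1 of them, were fatty acid genes (0.0653) without wild-type replicate 1 (0.0495) or 3 (0.0274) or floxed-labelled replicate 1 (0.0496) or 2 (0.0492), and the unfolded protein response (0.0722) without wild-type replicate 2 (0.0421) or 3 (0.0236) or floxed-labelled replicate 1 (0.0145). Cholesterol synthesis (0.0836) and Nrf2 targets (0.177) were called without wild-type replicate 1 (0.0411 each) or floxed-labelled replicate 2 (0.0238 and 0.0221), erythroid genes (0.0836) without wild-type replicate 1 (0.0139) and NF-kB targets (0.148) without floxed-labelled replicate 1 (0.0299). The count of 1642 fell to 1004 without wild-type IL-33 replicate 2 and to 1092 without floxed-labelled IL-33 replicate 3.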

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

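Of the tests in this part, those of the genes near Il1rl1, of sex, of an evenly weaker response and of the genes shared with IL-4 were chosen after the results had been seen, and those of substrain, of starting level and of regrouped libraries before. The values below stood out because the test of the difference between genotypes in the response to IL-33 was passed.

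In ST2KO-labelled cells the response to IL-33 differed from that of the wild type for 3284 genes. The difference was -9.40 log2 units for Arg1, -4.68 for Irg1, -1.09 for Chil3 and 0.71 for Cx3cr1. Rises were lost for Serpinb2 (-10.10), Ccl8 (-8.96), Slc13a3 (-7.14) and Mmp14 (-6.80). Falls were lost for Dkk2 (3.997), Tox2 (3.58), Cmah (3.55) and Angptl4 (2.97).

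In floxed-labelled cells, which differed from the wild type in sex as well, the response differed for 176 genes. The differences were -1.19 for Il1rl1, 1.48 for Dkk2, 0.99 for Tusc1, -2.05 for Tmem26, -1.91 for Clec4b1 and -1.79 for Slc22a4. Those of Slc5a3 (1.497), Gdf15 (1.222), Clec4n (0.98), St8sia1 (-2.10) and Ear2 (-2.03) were less firm, because each lost its call in 8 or more of the alternative fits.

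Regrouping the libraries gave a measure of what sample structure alone can produce. For pairs of groups there are only 10 splits, which cannot give a share under 0.05. The real grouping called 5122 genes for IL-33 and 6890 for IL-4 in wild-type cells, where the highest other split called 0 and 1, and 5772 for IL-33 against IL-4, where it called 2. It called 4835 in floxed-labelled cells with IL-33 (highest other 0), 196 and 1425 for the ST2KO-labelled and floxed-labelled cells without cytokine (0 and 0), and 1642 for the genotypes under IL-33 (1). In ST2KO-labelled cells with IL-33 the real grouping called 0 and the highest other 1, so all 10 splits called as many. For the interactions, 7 of 100 splits called as many genes as the real grouping in each case, and every other split that called as many either exchanged whole groups or left the libraries of 1 treatment as they were. The difference between the genotypes in that treatment stays in such a contrast by design, so these splits do not exclude chance and do not speak for it either. The highest other split called 4088 genes for ST2KO-labelled and 2755 for floxed-labelled cells. Both exchanged the whole groups with IL-33, which turns the contrast into the sum of the genotype differences without and with IL-33, so the structure they point to is that of the groups. The next highest called 3889 and 783, and splits that mixed the genotypes in both treatments called at most 0 and 1. Such mixing puts group differences into the spread, so low counts decide nothing either.

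The first pattern weighed was the difference between ST2KO-labelled and wild-type cells without cytokine. If DNA around the targeted gene had been carried over from another strain, or if the targeted allele had changed its neighbours, calls would gather near Il1rl1. Within 10 Mb lay 4.08% of the called genes (8 of 196) against 0.588% of the uncalled ones (Fisher's exact p = 3.5e-05). This share missed the 5% set for the test, and a window of the same size on chromosome 17 held more calls, 10 among 241 tested genes against 8 among 92 near Il1rl1. Carried-over DNA and an effect of the allele cannot be told apart, as both place calls in the same window and no variants were examined. The other 95.9% of the calls (188 genes) lay elsewhere, and the place of a call does not settle their origin. Linked DNA may run past 10 Mb, and changed neighbours such as Il1r1 may act on distant genes.

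The second pattern was the difference between floxed-labelled and wild-type cells without cytokine. Sex could explain genes on X and Y, as Xist and Y-linked genes followed genotype in all 21 libraries. X held 3.86% of called and 3.26% of uncalled genes (Fisher's exact p = 0.243), no clear excess. For the 1364 called genes not placed on X or Y, sex and genotype cannot be told apart, as they coincided. C57BL/6 substrain was tested with Wdfy1, Ide and Entpd4, of which the 2 measured gave 0 calls. Substrain stayed open, as Entpd4 was not measured and Nnt, another substrain marker, was 2.33-fold lower in floxed-labelled cells.

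The third pattern was the 73 genes with a smaller rise under IL-33 in floxed-labelled cells. An evenly weaker response stayed open. Of the genes raised at least 2-fold in the wild type, 5 rose more in floxed-labelled cells and 35 less, and the number of calls depended on single libraries. A higher starting level was less likely the main reason. The median log2 ratio of floxed-labelled over wild-type cells under IL-33 was -0.51 (interquartile range -0.74 to -0.28). There 56 of 73 genes were called lower. Selection on smaller rises favours such values. A higher start can hold for part, since without cytokine the ratio was 0.13, 26 genes were called higher and 23.3% met the terms set. A smaller response of genes that IL-4 also raises stayed open, as the values go both ways. Among genes raised at least 2-fold by IL-33, the median log2 ratio of levels under IL-33 was -0.23 for those that IL-4 also raises at least 2-fold and -0.25 for those it does not raise, a difference of 0.0182 (permutation p = 0.765), and the median differences in response were -0.44 and -0.51. Yet IL-4 raised 33 of the 73 genes at least 2-fold (45.2%), against 15.1% of the other genes raised by IL-33 (Fisher's exact p = 1.9e-09). Among genes raised at least 2-fold by IL-33 the shares were 68.6% (24 of 35) and 44.3% (253 of 571, Fisher's exact p = 0.0079). These shares rest on the same unstimulated wild-type libraries as the smaller rises, which by itself favours such an overlap. The reason for the smaller rises was left open.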

How the results depend on the processing

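Most counts kept their size under the alternatives, and the smaller ones moved. Without an expression filter the ST2KO-labelled response to IL-33 rose from 0 to 70 calls, the Gata3 interaction to 555 and the unstimulated ST2KO-labelled difference to 875; DESeq2 gave 384 and 438 for these last comparisons, and the cause was not tested. A replicate block gave 355 calls for the Gata3 interaction and 590 for the unstimulated ST2KO-labelled difference, yet deviations from the group means were hardly correlated between libraries sharing a number (median 0.0257, range -0.0399 to 0.110) and not every library correlated best with its own number, so the numbers were not taken as pairs. Of the genes named in every comparison, the block also called Irg1 with IL-4 (0.67) and Cx3cr1 in the Gata3 interaction (-0.59) and in unstimulated floxed-labelled cells (0.31). Of 261 list tests 104 were called, and with an estimated correlation 15. With 1 library left out, the calls ranged from 4358 to 4721 (wild type, IL-33), 6165 to 6517 (IL-4), 4980 to 5535 (IL-33 against IL-4), 0 throughout (ST2KO-labelled, IL-33), 4053 to 4530 (floxed-labelled, IL-33), 2733 to 3410 (ST2 interaction), 52 to 273 (Gata3 interaction), 54 to 208 (ST2KO-labelled, unstimulated), 658 to 1239 (floxed-labelled, unstimulated) and 1004 to 1458 (floxed-labelled against wild type under IL-33). Genes moving alike with both cytokines ranged from 2599 to 2963 and called lists from 99 to 107. The Gata3 interaction fell to 62 and 65 without unstimulated wild-type replicate 1 or 3, 54 and 112 without wild-type IL-33 replicate 2 or 3 (273 without replicate 1), 92, 85 and 109 without unstimulated floxed-labelled replicate 1, 2 or 3, and 77 and 52 without floxed-labelled IL-33 replicate 1 or 3. The interferon-stimulated list in ST2KO-labelled cells with IL-33 had an adjusted p of 0.994. Without unstimulated replicate 2 it was called in the other direction (1.0e-05), and without unstimulated replicate 3 it was 0.776. The cause of these changes was not tested. Without genes of X and Y, 1347 genes were called for unstimulated floxed-labelled cells, 174 for the Gata3 interaction and 1575 under IL-33, and without genes near Il1rl1 187 for unstimulated ST2KO-labelled cells.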

Other observations

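The genes in this part were chosen after their values had been seen, and no explanation was tested on them beyond the comparisons described. Cytokine genes of type 2 lymphoid cells appeared with IL-33. Il13 was at 2.89 ± 0.156 CPM in wild-type cells with IL-33 (107 to 113 counts per library, adjusted p = 3.7e-07) and had 0 counts without cytokine and with IL-4. In floxed-labelled cells with IL-33 it was at 1.502 ± 0.542 CPM, against 0 counts without cytokine. In the wild type, Il9 (43 counts over 3 libraries with IL-33, adjusted p = 0.00142) and Il5 (38 counts, 0.00430) also had 0 counts without cytokine and with IL-4, and Csf2 (30 counts, 0.00230) had 0 and 1. Exons of Il5 overlap another gene and its call was lost with DESeq2. In ST2KO-labelled cells with IL-33, Il13, Il9 and Csf2 had 0 counts and Il5 had 4, all in 1 library. The STAT5 target genes Cish and Socs2 rose 44.8-fold and 31.3-fold with IL-33 and 151-fold and 41.4-fold with IL-4. The basophil and mast cell genes Mcpt8 (0.389 ± 0.143 CPM) and Ms4a2 (0.336 ± 0.0747 CPM) also rose with IL-33 in the wild type (adjusted p = 0.00395 and 0.00716), in a list that was not called and in which Kit fell 4.68-fold. In floxed-labelled cells with IL-33 they were at 0.966 ± 0.121 and 1.21 ± 0.363 CPM, not called higher (adjusted p = 0.137 and 0.0738). Kit was 2.40-fold higher than in the wild type (0.0121), and the list was called higher (0.0077, but 0.22 with an estimated correlation). Mcpt8 was also 5.56-fold higher in unstimulated floxed-labelled cells (0.303 against 0.0510 CPM, adjusted p = 0.0374), a call lost in all 6 fits with 1 library left out.

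The efferocytosis receptor gene Timd4 had 30 to 56 counts per library in unstimulated floxed-labelled cells (0.880 ± 0.224 CPM, adjusted p = 0.000690) and 67 to 94 with IL-33, and was at or below 0.058 CPM in wild-type and ST2KO-labelled groups. Nnt, which encodes a mitochondrial transhydrogenase, stood at 85.9 ± 3.97 CPM in unstimulated wild-type and 36.9 ± 3.52 CPM in floxed-labelled cells, 2.33-fold lower (adjusted p = 9.2e-12). Wdfy1 was lower in ST2KO-labelled cells (32.8 against 56.1 CPM, adjusted p = 7.4e-09) and not in floxed-labelled ones (54.6 CPM, 0.706). The chemokine gene Ccl24 rose 4.26-fold with IL-33 and 13.05-fold with IL-4.

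A hypothesis is that a few innate lymphoid cells in the cultures responded to IL-33 and passed IL-13 on to the macrophages. Arg1 and Mgl2, raised by both cytokines, might then be indirect. A lower mean of Il13 in floxed-labelled cultures, which differed in sex, may be linked to their lower Arg1. Mgl2 was 2.01-fold lower in floxed-labelled cells under IL-33 (2.0e-06), with a smaller response (-0.73, adjusted p = 0.0487) whose call was lost in 12 of 20 alternative fits. Ccl24 was 2.11-fold lower (0.0340), without a called difference in response (0.991). Chil3 was 1.79-fold higher, as it was without cytokine (1.86-fold). Cish and Socs2 were not called lower (adjusted p = 0.601 and 0.679). The lymphocyte and innate lymphoid list was not called with IL-33 in the wild type (adjusted p = 0.99), nor was Gata3 (0.74). The Il13 difference between the genotypes under IL-33 did not pass (adjusted p = 0.146). The test of genes that IL-4 also raises left this reading open for the smaller rises in floxed-labelled cells. Mcpt8, Ms4a2 and Kit were not lower in floxed-labelled cells, but nor was Gata3, so mast cells or basophils stay open too. Blocking IL-13 or IL-4 receptor chains during IL-33 treatment, or sorting macrophages before adding IL-33, would test it. A further hypothesis is that Nnt marks a difference of substrain or allele number between the colonies. Against the wild type, the substrain test of floxed-labelled cells gave 0 calls among the 2 genes measured, while in ST2KO-labelled cells Wdfy1 was called lower (-0.77) and so was Nnt (-0.28, adjusted p = 0.0273). Wdfy1 lies on chromosome 1 as Il1rl1 does, so linked DNA may equally account for it. Sequencing of these loci in each colony would settle this.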
